A study of Arabidopsis thaliana with 6 samples.

How the data were processed

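Total RNA from rosette leaves of Arabidopsis thaliana was labelled with biotin and hybridised to ATH1 expression arrays, 1 sample per array. By the labels, 3 samples came from wild-type Col-2 plants and 3 from the pho1 mutant, and both groups carry the replicate numbers 1, 2 and 3. The labels do not say whether the replicates came from separate plants or trays, so the p-values measure the spread between these samples, which may be technical. The deposited values are linear intensity values per probe set (a group of short probes read out as a single number), made with MAS5 per the submitters' processing notes; its version is not given in the sources used here. The table held 22810 probe sets, of which 64 were control probe sets, and had no columns of other samples. The trimmed mean of each array, leaving out the lowest and highest 2% of values, was 100.01, so the arrays had been brought to a common level before deposit. No detection calls were used here, and the number of arrays limits the precision.

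Arrays were scaled to the mean of their trimmed means, which changed almost nothing, and log2(signal + offset) was taken with an offset of 10% of that mean. Fold changes are on this log2 scale and understate the change of dim probe sets. Control probe sets were left out, and the 15922 probe sets at or above the 30th percentile of mean log2 value were tested, a limit that lies at a signal of 17.4. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, no block), with Benjamini-Hochberg adjustment and a threshold of 0.05. Plots were drawn with matplotlib 3.10.9. The procedure was tested on simulated arrays with the real means and spreads of the 15922 probe sets, 200 of them changed in each of 5 runs. It found 0.80% of changes of 0.5 on the log2 scale, 33.6% of changes of 1, 82.8% of changes of 2 and 93.2% of changes of 3, and 2.95% of its calls were false. The simulated noise was independent between probe sets and alike on all arrays. The real arrays differ from this, as both replicate 1 arrays stood apart, so these rates need not hold for them.

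Probe sets were named only through the platform annotation given, updated through a RefSeq gene table of the TAIR10.1 assembly. Of the 22746 probe sets other than controls, 13513 had 1 gene, 503 had several and 8730 had none listed; 13436 of those with 1 gene matched a locus. Many well-known genes are among those not listed, and no probe set is paired with PHO1 itself, so its transcript is not analysed here. Of 95 loci with several tested probe sets, 2 had a call, and in neither did the probe sets differ in sign. Before the data were examined, 27 gene lists with 464 entries were written down, of which 57 entries had a named probe set. Lists with at least 3 tested members were tested with camera (preset inter-gene correlation of 0.01), with 1 probe set per locus. A further 17 lists were written after the annotation and the first rows of the value table had been seen and before any test was run, because so few entries of the first lists were named. They are called added lists. The plan was a single adjustment over all lists and was written when only the first lists existed. Adjusting the first and the added lists apart was settled after a run over all of them together had been seen, in which the anthocyanin list did not pass (adjusted p = 0.054); both values are given. The genes named in the text are PHO1, the 12 largest rises and 12 largest falls among called probe sets with 1 gene and no overlap between groups, and for each list up to 4 called members or, where none was called, the 2 members with the smallest p. This rule was also applied to the added lists. Some genes it picked there are left out of the text but enter the counts of named genes. Members of short lists that the text names beyond the rule were chosen after their values were seen.

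Deviations of same-numbered samples from their group means were correlated across probe sets. The values were 0.42 for replicate 1, 0.22 for replicate 2 and 0.39 for replicate 3. The numbers were taken to pair the samples in the replicate block and in the differences by replicate. The main fit has no block, so its p-values leave this pairing out. Across numbers, pho1 replicate 2 and wild type replicate 3 correlated at 0.33, and wild type replicate 2 and pho1 replicate 3 at 0.022. The values thus set replicate 1 apart but do not clearly tell pair 2 from pair 3. The pairing comes from the data and not from the labels. No pair of arrays held identical tables; arrays of the same group correlated at 0.92 to 0.98. The alternatives tried were other scalings, offsets, filters, variance models and thresholds, the replicate block, leaving out each array and other set tests. Chosen after the data had been seen were the added lists, the adjustment of both families of lists apart or together, a block for a possible batch seen in the spike-in controls, and replicates 2 and 3 on their own.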

Results

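Transcript levels were measured on 6 arrays, 3 of wild-type Col-2 rosette leaves and 3 of pho1 rosette leaves. The pho1 mutant was made in the same background by chemical mutagenesis and is short of phosphate in the shoot. The plants were at growth stage 3.90, on 0.8% agar with MS salts and 1% sucrose, at 24 °C, 80% humidity and a 16 h photoperiod. Median signals of the arrays lay between 41.2 and 46.5. The comparison asks which leaf transcripts differ between the mutant and its wild type.

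In pho1 leaves, 417 probe sets were higher and 55 lower than in wild type, 472 of the 15922 tested (limma, adjusted p under 0.05). The changes upward were also larger, with 371 of the higher and 33 of the lower probe sets differing by at least 1 on the log2 scale. The 3 pho1 values lay wholly above or below the 3 wild-type values in 3161 of the tested probe sets, 19.85%, where chance gives 10%. With the replicate number as a block, 1057 probe sets passed, 788 higher and 269 lower. The split was near even in replicates 2 and 3 on their own (1547 higher, 1474 lower) and with array weights (1982 and 1807), and leaving out 1 array put the lower count between 3 and 280. A single gene was listed for 220 of the 472.

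The largest rise among named genes was that of AT5G20790, from a signal of 8.83 ± 12.4 in wild type to 1534 ± 682 in pho1 (SD, n = 3 each), a log2 difference of 6.44 ± 0.48 (SE; limma adjusted p = 3.8e-04). AT1G08310 rose by 5.09, and GAT1_2.1, which encodes a protein of the glutamine amidotransferase class, rose by 4.33 from 3.03 ± 1.01 to 252 ± 32.9. AT1G19200 rose by 4.26, AT1G68620 by 4.00, AT1G23140 by 3.86, AT3G43110 by 3.57, AT1G57630 by 3.43, AT5G52760 by 3.42 and AT5G55450 by 3.42. SAL2, a relative of the SAL1 phosphatase, rose by 3.76. AT1G13750 (PAP1), a purple acid phosphatase, rose by 3.5 from 41.4 ± 14 to 559 ± 28.5. The wild-type signals of most of these genes lay near or below the offset of 10, where the log2 difference understates the change. The calls of AT1G68620 and AT5G55450 ended under 3 and 5 of the 19 alternatives, with adjusted p up to 0.079 and 0.17; those of the other 10 genes held in each alternative that tested them. The largest rises among called probe sets with no gene listed were 6.55 and 6.27.

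**Figure D1:**
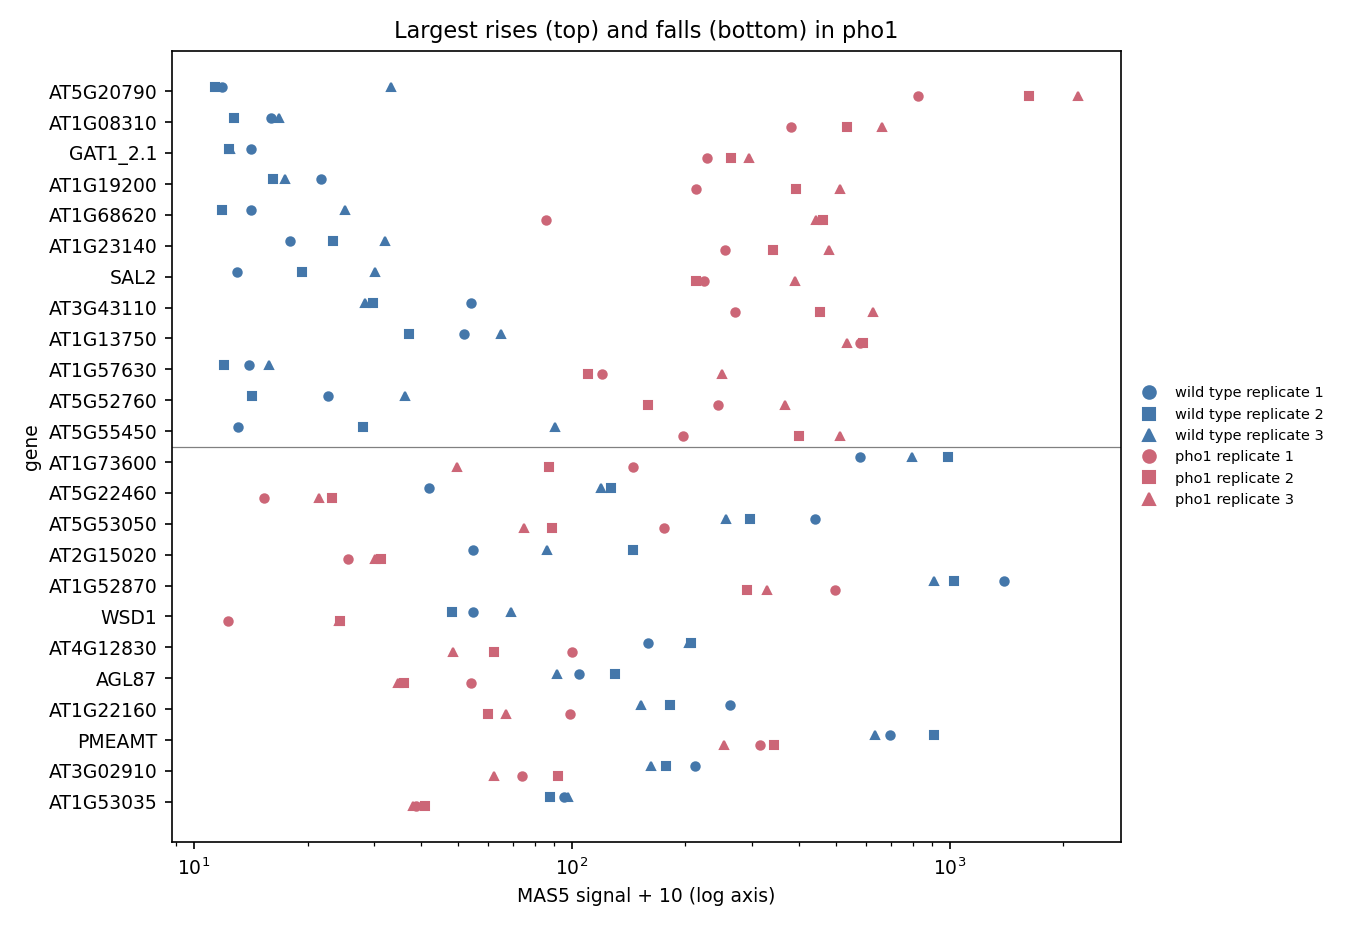
Signals plus 10 on a log axis for the 12 genes with the largest rises and the 12 with the largest falls in pho1, 1 point per array, with colour for the group and shape for the replicate number. The pho1 points of each gene lie wholly on one side of the wild-type points.

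The largest fall was that of AT1G73600 (NMT3), a phosphoethanolamine methyltransferase of phosphatidylcholine synthesis. Its signal was 780.1 ± 206 in wild type and 83.9 ± 48.0 in pho1, a log2 difference of -3.17 ± 0.38 (SE; limma adjusted p = 0.0040). PMEAMT, another enzyme of that family, fell by 1.29 from 736 ± 144 to 294 ± 46.2. AT1G52870 fell by 1.59 from a high wild-type level of 1100 ± 251. WSD1, a wax ester synthase, fell by 1.55, and the MADS-box gene AGL87 fell by 1.4. The log2 differences of the other falls were -2.13 for AT5G22460, -1.62 for AT5G53050, -1.61 for AT2G15020, -1.49 for AT4G12830, -1.4 for AT1G22160, -1.28 for AT3G02910 and -1.25 for AT1G53035. Only NMT3 and AT1G53035 of these 12 kept their call under all 19 alternatives; that of PMEAMT ended under 3, with adjusted p up to 0.093, and the highest adjusted p of any was 0.21 for AT5G53050. The largest falls among called probe sets with no gene listed were -2.40 and -2.27.

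Most tested genes of a phosphate starvation list were higher in pho1. Of 11 tested members of this added list, 8 rose and 1, NMT3, fell, with a median of 3.29 (camera adjusted p = 1.0e-13). The adjusted p = 0.13 with an estimated correlation did not pass, and fry's directional test gave 0.0019. The list's medians were 2.61, 3.32 and 3.52 in replicates 1, 2 and 3. Its members include AT5G20790, AT1G23140, SAL2, AT3G43110 and PAP1 of the largest rises, so the list and those genes are not separate results. The list was written after the annotation was seen and shares PAP1 and NMT3 with the lists fixed beforehand. Of those, phosphate starvation signalling had 2 tested members and neither passed: WRKY6 differed by 0.99 (adjusted p = 0.37, and 0.034 with the replicate block) and SIZ1 by 0.08. NMT3 was the only tested member of the membrane lipid list and PAP1 the only one of the phosphatase list. No phosphate transporter had a named probe set.

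The salicylate and pathogen response list has 20 entries, of which 3 were tested. These 3 lay higher in pho1, with a median of 1.22 (camera adjusted p = 0.0036, and adjusted p = 0.43 with an estimated correlation). Their medians were 0.30, 1.5 and 1.9 in replicates 1, 2 and 3. GRX480, a glutaredoxin gene induced by salicylate, rose by 2.29 from 33.0 ± 15.4 to 209.7 ± 110 (limma adjusted p = 0.028); its call ended with no filter (0.071), without wild type replicate 2 (0.095), without pho1 replicate 2 (0.12) and without pho1 replicate 3 (0.11). WRKY53 differed by 1.22 and SAG101 by 0.67, neither past the threshold over all probe sets. Both passed in replicates 2 and 3 on their own (1.70, limma adjusted p = 0.0084, and 0.85, adjusted p = 0.039). That was not particular to this list, as 3021 probe sets passed in that fit. Among them were 20 of the named genes that were not called over all arrays. Adjusted over the list alone, 3 of 3 passed. The anthocyanin and flavonoid enzymes had a median of 1.04 over 3 tested members of 17 entries, with 0.53, 1.6 and 1.3 in replicates 1, 2 and 3. Whether this list passed depended on the adjustment: camera gave an adjusted p = 0.054 over fixed and added lists together, which was seen first, and 0.039 over the fixed lists alone, a choice settled afterwards (adjusted p = 0.43 with an estimated correlation). The value over the fixed lists did not pass without wild type replicate 1 (0.24), without pho1 replicate 2 (0.0501), without pho1 replicate 3 (0.091), with array weights (0.12) and with the filter at the 50th percentile (0.074). None of its members passed over all probe sets and 2 passed adjusted over the list alone: UF3GT, an anthocyanin glycosyltransferase, differed by 1.33 (limma adjusted p = 0.15, and 0.0075 with the replicate block) and DFR, dihydroflavonol reductase, by 1.04. UF3GT and DFR passed in replicates 2 and 3 on their own (limma adjusted p = 0.022 and 0.0091).

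No call was made for the other 5 lists that could be tested. The 9 nuclear photosynthesis genes had a median of 0.04 (camera adjusted p = 0.85), with camera's direction down, and included SBPASE at -0.56 and LHCB4.2 at 0.28. SBPASE passed in replicates 2 and 3, at -0.80 (limma adjusted p = 0.019), and LHCB4.2 did not. Of the 5 starch genes 4 lay below 0 (median -0.47, adjusted p = 0.27), with PWD at -0.61 (limma adjusted p = 0.15, and 0.049 with the replicate block) and DPE1 at -0.47. The 4 genes of the abscisic acid, cold and drought list all lay below 0 (median -0.29, adjusted p = 0.50). Their lowest member, COR47, differed by -1.01 (limma adjusted p = 0.36, and 0.0079 with the replicate block), and LTI30 by -0.26. COR47 also passed in replicates 2 and 3 (limma adjusted p = 0.014). Phosphate-sparing carbon metabolism had a median of 0.09 over 5 genes (adjusted p = 0.69), with PPDK at 0.31 and ALDH11A3 at 0.27. Glucosinolate synthesis had a median of 0.02 over 3 genes and a camera direction of down (adjusted p = 0.64), with AT2G31790 (UGT74C1) at -0.47 and BCAT4 at 0.06. UGT74C1 passed in replicates 2 and 3, at -0.57 (limma adjusted p = 0.033). Adjusted over the list alone, no member of these 5 lists passed.

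Other lists had 2 or fewer tested members and no test of the list. The expansin EXPA8 had a signal of 1059 ± 211 in wild type and 394 ± 264 in pho1, a log2 difference of -1.57 (limma adjusted p = 0.090, and 0.037 with the replicate block). The small heat shock gene AT5G37670 differed by 1.00 (adjusted p = 0.075) and ATHSP22.0 by 0.08. Differences were -0.38 for the iron regulator PYE, 0.15 for APS3 and -0.17 for BGLU28 of the sulfate list, -0.43 for the defensin PDF1.2, -0.06 for the replication gene PRL (MCM7) and 0.16 for the clock gene GI, none past the threshold over all probe sets. In replicates 2 and 3 GI was at 0.59 and passed (limma adjusted p = 0.030), as did EXPA8 at -2.11 (8.1e-04) and AT5G37670 at 1.18 (0.019). Adjusted over the list alone, EXPA8, AT5G37670 and PYE passed, as did PAP1 and NMT3; each was alone in its list but AT5G37670, so no adjustment was made for them. Of the cell type markers, the root gene PYK10 differed by 0.80 (adjusted p = 0.35), the guard cell gene FMA (FAMA) by 0.28 and the trichome gene TRY by -0.54; none passed, over all probe sets or over the list alone. The senescence and floral lists had a named probe set each but none bright enough to be tested, and the nitrogen, anthocyanin regulator, phloem and xylem lists had none named.

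**Figure D2:**
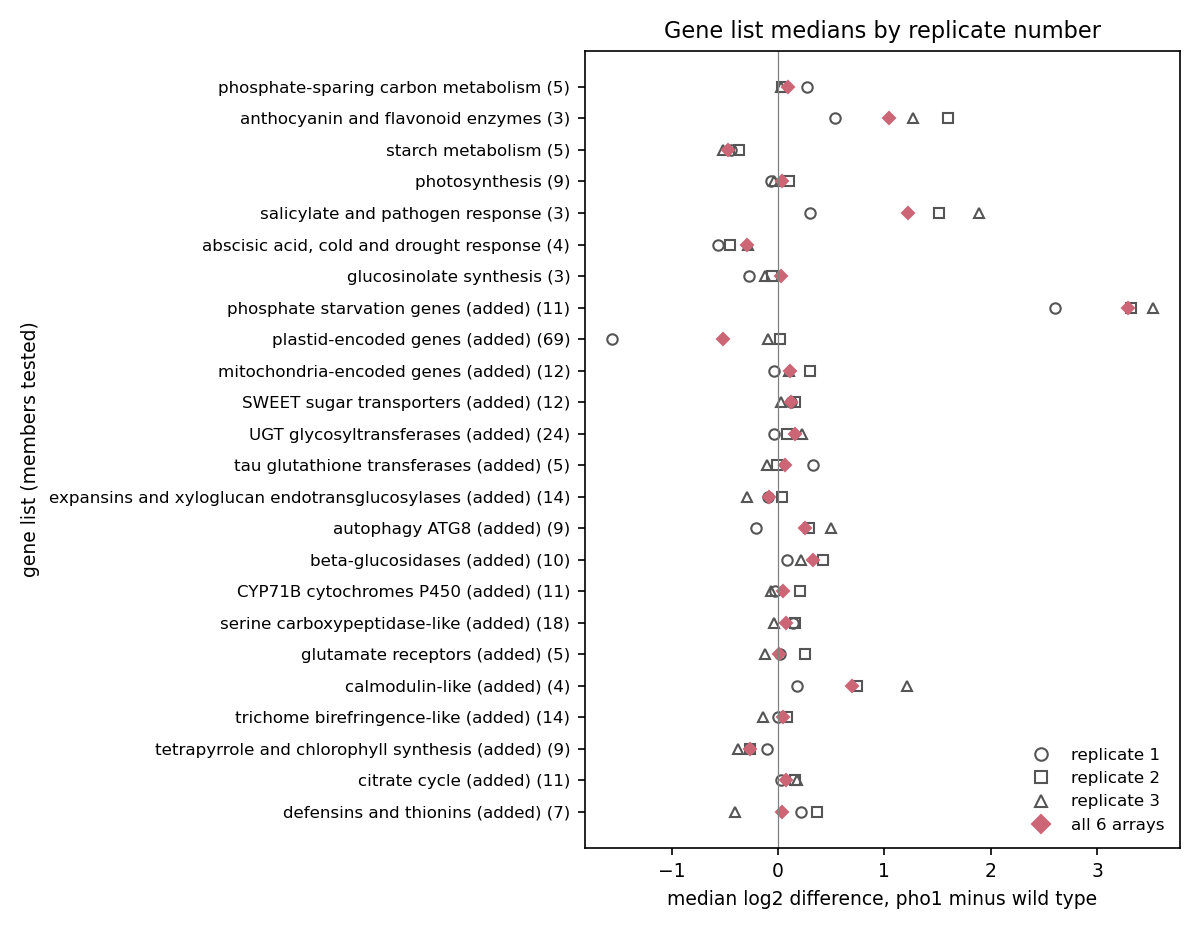
Median log2 difference, pho1 minus wild type, of each gene list with at least 3 tested members, for each replicate number (open symbols) and for the fit to all 6 arrays (filled diamonds). The phosphate starvation genes lie between 2.61 and 3.52 in the replicates, and the plastid-encoded genes reach -1.56 in replicate 1 alone.

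Both replicate 1 arrays stood apart from the rest. Median signals were taken over 12 control probe sets of the bacterial spike-ins dap, lys, phe and thr. They were 4.00 in wild type replicate 1 and 2.15 in pho1 replicate 1, against 52.4 to 92.8 on the other 4 arrays. Other spike-in controls, such as bioD and cre, were not low there. A bioD 3' probe set was at 1136 in wild type replicate 1 and 1342 in pho1 replicate 1, against 439 to 651 elsewhere. The labels name no batch. The 12 controls part the arrays into sets that each hold both groups. With the sets as a block, 1319 probe sets passed, 900 higher and 419 lower. Replicates 2 and 3 on their own gave 3021; replicate 1 has 1 array per group and allows no test. Single arrays also moved the count: it was 182 without wild type replicate 2, 303 without wild type replicate 3, 161 without pho1 replicate 2, 162 without pho1 replicate 3 and 1040 without pho1 replicate 1. In replicates 2 and 3, AT5G20790 differed by 6.60, GRX480 by 2.84 and NMT3 by -3.76. The salicylate list (camera adjusted p = 0.016), the anthocyanin list (0.017) and the phosphate starvation list (6.2e-08) passed there, the anthocyanin list with 5 tested members in place of 3 and both it and the salicylate list adjusted over the fixed lists alone; they also passed with the sets as a block. Over all arrays none of the 3 passed with an estimated correlation (adjusted p = 0.43, 0.43 and 0.13).

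**Figure D3:**
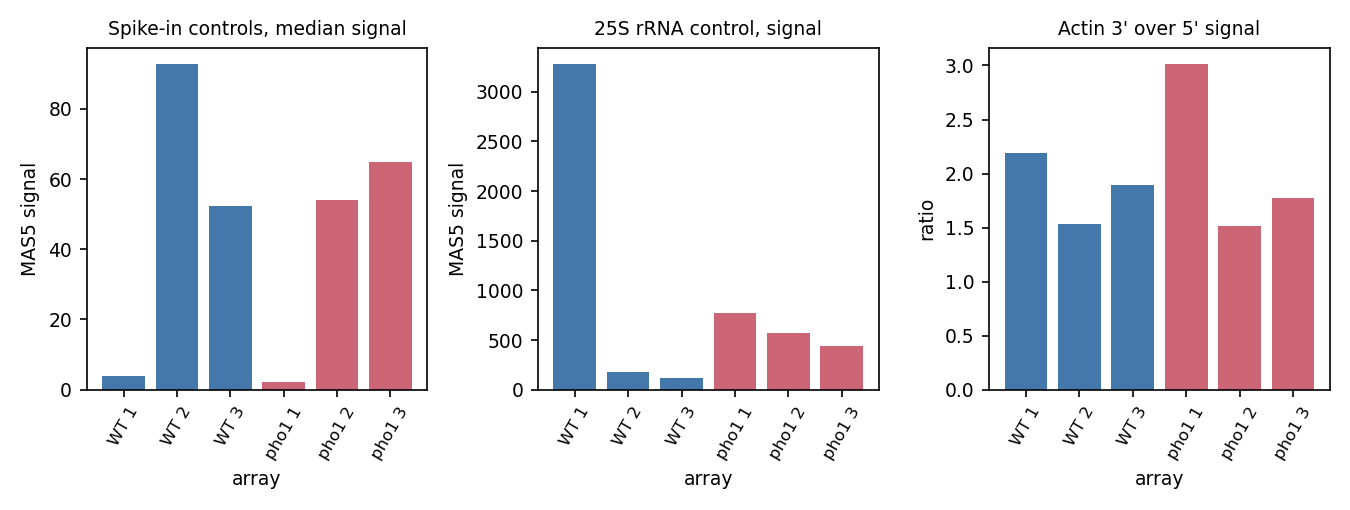
Median signal of 12 dap, lys, phe and thr spike-in controls, signal of the 25S ribosomal RNA control, and the ratio of actin 3' to 5' signal, 1 bar per array (WT, wild type). The signal of these spike-ins is near 0 on both replicate 1 arrays. The ribosomal RNA control reaches 3279 in wild type replicate 1, and the actin ratio is highest, at 3.01, in pho1 replicate 1.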

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

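Chosen only after the results were seen were the count over all arrays for RNA without a poly(A) tail and the share of rises within replicates 2 and 3. There were 34 control probe sets with a mean signal of at least 100, which enter no comparison above. Of these, 4 had all pho1 arrays above all wild-type arrays. On the log2 scale the 4 differed by 0.32 (GAPDH 3'), 0.43 (ubiquitin middle), 0.11 (actin 3') and 0.23 (ubiquitin 5'). Chance gives 1.70 (5%) for this direction alone, and a share of 10% for no overlap in either direction. The 34 mix probe sets of plant genes with spike-in controls, and the 4 are all of plant genes. Second bright probe sets of GAPDH 3', actin 3' and ubiquitin 5' differed by 0.29, 0.07 and 0.34 but overlapped between groups. The ubiquitin probe sets may also not be independent, so an excess over chance is not shown.

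Plastid-encoded transcripts, an added list of 69 genes, lay lower in pho1 (median -0.52, camera adjusted p = 5.6e-05, and adjusted p = 0.67 with an estimated correlation). Array medians were 380 in pho1 replicate 1 and 1209 to 1612 on the other 5 arrays. The median difference in replicates 2 and 3 was -0.0084, so the difference of the list came with replicate 1. Wild type replicate 1, which also lacked the dap, lys, phe and thr spike-in signal, was at 1612, the highest of the 6. Carry-over of RNA without a poly(A) tail stays open. In pair 1 the 25S ribosomal RNA control and the plastid median were both lower in pho1 (-2.09 and -1.56). The control was higher by 1.70 in pair 2 and by 1.86 in pair 3, with plastid medians of 0.02 and -0.09. The bound set against carry-over, a plastid median below -0.2 with a higher control, was met by 0 pairs. Over all arrays, 4 had a lower control than pho1 replicate 1 and a higher plastid median. That met the bound set against carry-over for this later count. The 4 arrays are all of replicates 2 and 3, whose spike-in signals differ from those of pho1 replicate 1, so the count cannot decide. RNA quality also stays open. The actin 3' to 5' ratio was highest in pho1 replicate 1 (3.01), and 0 pairs with near-equal actin ratios had a plastid median below -0.2. However, wild type replicate 1 had the next highest actin ratio (2.19) and the highest plastid median. The GAPDH 3' to 5' ratio set pho1 replicate 1 less apart (1.17, against 0.93 to 1.09 on the other arrays). For the list as a whole, an effect of the pho1 genotype on all replicates has only pho1 replicate 1 behind it. The list's call ended without pho1 replicate 1 (camera adjusted p = 0.23) and with array weights (0.56). The 2 members with the smallest p, neither called, were lower in every pair: ndhE by -2.39, -0.55 and -0.64, and ndhF by -1.16, -0.61 and -0.31. In replicates 2 and 3 ndhE passed, at -0.60 (limma adjusted p = 0.020), and ndhF did not (0.13).

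More probe sets rose than fell in pho1, 417 against 55. The share of rises was at least 84.4% under every other scaling, although the use of values as deposited moved nothing. It thus did not rest on the choice among these scalings. They moved the median difference over all tested probe sets only from -0.021 to -0.062 (quantile) and -0.093 (median centring). As 404 of the 472 calls differed by at least 1 on the log2 scale, such shifts could hardly change the share. The check thus cannot decide on array scaling. An effect of the offset on dim probe sets is argued against by a share of 83.5% (exact 95% interval 76.0 to 89.3) among calls with both group means at 100 or more. The interval counts probe sets as independent and does not measure the spread between arrays. Within replicates 2 and 3 the share was 51.2%, so the spread of replicate 1 may have hidden many small falls: rises made up 75.7% of the calls there of at least 1 on the log2 scale and 37.6% of the smaller ones. A difference of the genotype in large changes stays open and was not tested apart from this.

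The 6 arrays make 10 splits into 3 and 3. The real split gave 472 calls and the highest of the others gave 1; 1 of 10 splits gave as many calls as the real one, itself, and 10 splits are too few for a share under 0.05. Of the 4 splits that part every pair of replicate numbers, the other 3 gave 0 calls with limma, and those that part 1 pair gave 0 or 1. All these counts are of the fit without a replicate block. Each split but the real one has both groups on each side, so the group difference widens the spread there. Few calls in those splits would thus be seen in any case.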

How the results depend on the processing

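The block for the spike-in sets, replicates 2 and 3 alone, the added lists and the adjustment of fixed and added lists apart were chosen after the data were seen. The 472 calls (417 higher, 55 lower) stayed within 1.5 times under the other scalings and offsets, the filter at the 50th percentile, and eBayes without a trend or robust. The values as deposited changed nothing and test nothing. With no filter there were 289 calls (263 higher, 26 lower), with more dim probe sets tested; with array weights, which set both replicate 1 arrays below 0.32, 3789 (1982 and 1807); with the replicate block 1057 (788 and 269); at a threshold of 0.10, 778 (631 and 147); with a log2 change of at least 1, 33 lower; with the block for the spike-in sets 1319 (900 and 419); in replicates 2 and 3 alone 3021 (1547 and 1474). The spread within groups was 0.25 over all arrays and 0.15 in replicates 2 and 3. Leaving out 1 array gave 161 to 1040 calls, 156 to 760 higher and 3 to 280 lower.

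Of the fixed lists 2 were called; 0 were with the filter at the 50th percentile (where the salicylate list had too few members), an estimated correlation, fry directional or fry mixed, 1 with array weights or 1 adjustment over all lists, and 1 to 2 without 1 array. Of the added lists 3 were called, 0 with an estimated correlation, 1 with fry directional, 4 with fry mixed (the phosphate starvation, beta-glucosidase, trichome birefringence-like and defensin lists), 4 with no filter (glycosyltransferases gained) and 2 to 4 without 1 array. The replicate block changed no list call. The PHO1 transcript has no value under any setting.

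Of 34 called genes and probe sets named in the text, 14 stayed called in the same direction under every alternative that tested them and 21 under those that keep all arrays. Of the named genes that were not called, 27 passed with array weights, 20 in replicates 2 and 3, 10 with the block for the spike-in sets, 9 without pho1 replicate 1, 8 with the replicate block, and 1 each with quantile normalization and median centring. Signs turned only for 9 genes that were not called. With array weights LTI30 was at 0.16, ATHSP22.0 at -0.030 and the glutathione transferase GSTU20 at 0.088; with median centring BCAT4 was at -0.0073; in replicates 2 and 3 LTI30 was at 0.44 and ATHSP22.0 at -0.073. Over the fits without 1 array, APS3 ranged from -0.033 to 0.34, BGLU28 from -0.41 to 0.11, PDF1.2 from -0.89 to 0.058, LTI30 from -0.64 to 0.44, ATHSP22.0 from -0.18 to 0.23, BCAT4 from -0.094 to 0.19, PRL from -0.17 to 0.068 and GI from -0.19 to 0.81. The cause was not tested for these. Signals near the offset limit the fold of the dimmest genes.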

Other observations

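All results here are of added lists, tested as the fixed ones. Calmodulin-like genes lay higher in pho1 (median 0.70 over 4 tested members, camera adjusted p = 0.027, and adjusted p = 0.67 with an estimated correlation). The list's medians were 0.18, 0.75 and 1.2 in replicates 1, 2 and 3. Of these genes CML41 rose by 1.61 from 38.0 ± 16.5 to 137 ± 52.1 (SD, n = 3). The call ended with the filter at the 50th percentile (adjusted p = 0.075), without pho1 replicate 2 (0.063) and without wild type replicate 3 (0.081). Single members of other lists rose: the beta-glucosidase BGLU44 by 1.28, from 797 ± 47.1 to 1976 ± 385; the defensin-like LCR68 by 1.37, from 570.2 ± 63.8 to 1502 ± 313; the cytochrome P450 CYP71B23 by 2.26; and TBL37, of the trichome birefringence-like family, by 1.39. Each of these 4 calls ended under 4 or 5 of the 19 alternatives, with adjusted p up to 0.14, and that of CML41 under 7, with adjusted p up to 0.22. The lists of BGLU44, LCR68, CYP71B23 and TBL37 were not called (camera adjusted p = 0.15, 0.35, 0.69 and 0.69); fry mixed, which tests change in either direction, gave adjusted p = 0.032, 0.032, 0.051 and 0.021.

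The sugar transporter SWEET11 had a signal of 564 ± 41.8 in wild type and 951 ± 86.4 in pho1 (log2 difference 0.74, limma adjusted p = 0.070, and 0.031 with the replicate block). The 12 SWEET genes had a median of 0.12 (camera adjusted p = 0.35), with SWEET16 at 0.23. The glycosyltransferases (median 0.16 over 24, adjusted p = 0.33, and 0.027 over 47 with no filter) included UGT87A2 at 1.56 (limma adjusted p = 0.083, and 0.013 with the replicate block) and UGT72E1 at 0.67. The 9 ATG8 autophagy genes had a median of 0.26 (adjusted p = 0.24, 0.022 in replicates 2 and 3, and 0.020 without wild type replicate 1), with ATG8H at 1.09 (1.76 in replicates 2 and 3, limma adjusted p = 7.5e-04) and ATG8B at 0.38. Tetrapyrrole and chlorophyll synthesis lay below 0 in 8 of 9 genes (median -0.27, adjusted p = 0.14), with CHLI2 at -0.50 and HEMB1 at -0.40. CHLI2 passed in replicates 2 and 3, at -0.74 (limma adjusted p = 0.030). Among expansins and xyloglucan endotransglucosylases (median -0.09 over 14, adjusted p = 0.35), EXPB3 was at -0.89 (limma adjusted p = 0.069, and 0.046 with the replicate block). Mitochondria-encoded genes had a median of 0.11 (12 tested, adjusted p = 0.35), with cox1 at 0.57 and cox2 at 0.50.

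The remaining added lists had medians of 0.07 (tau glutathione transferases, adjusted p = 0.71), 0.08 (serine carboxypeptidase-like, 0.58), 0.01 (glutamate receptors, 0.58) and 0.08 (citrate cycle, 0.69).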
